A study of Mus musculus with 6 samples.

How the data were processed

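The deposited table holds 1 value per transcript cluster and array, on the log2 scale, for 6 Affymetrix Mouse Gene 1.0 ST arrays. Per the labels' protocols, total RNA of testes was extracted with Trizol, purified on columns and labelled with biotin. Per the submitters' processing notes the authors used RMA (background correction, quantile normalisation and summary over probes, on the log2 scale) in Affymetrix Expression Console. Versions, the probe annotation and the genome build are not given in the sources used here. The values had 2 decimals and ran from 2.19 to 14.02, and the quartiles of the arrays were alike, as quantile normalisation leaves them. RMA makes the arrays share 1 distribution, so a change of all transcripts together would not be seen, and it compresses differences of dim clusters. Detection p-values, scanner files and scan dates were not used here, so the background and hybridisation batches are not known.

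Samples were grouped by the genotype in their labels, 3 control and 3 knockout, with the replicate numbers of the labels. The highest share of identical values between any pair of arrays was 4.92%, so no array was a copy of another. Clusters were named through the platform annotation: of 35556 rows, 21789 had 1 gene symbol, 1621 had several and 12146 were not named. Rows with several symbols or none, 13767 in all, were left out of the test. Symbols were updated through gene identifiers to the gene table of assembly GRCm38.p6, in which 21698 tested clusters matched. That table also gave the chromosome of each gene; none of its coordinates is printed because the build of the array design was not named. Members of the fixed lists without a measured cluster were not analysed here. The targeted gene and the test of genes near it are not reported here, and the array values were not used to check the genotype labels.

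Knockout was compared with control in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over the 21789 clusters and a threshold of 0.05. The fit had 4 residual and 3.24 prior degrees of freedom. Differences are knockout minus control on the log2 scale, folds are knockout over control, and n is 3 arrays per group. For tests of gene lists, a gene with several clusters (999 genes) was represented by the cluster with the highest mean over all arrays. The lists were tested against all other genes with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over 22 lists. Beside it, camera was run with the correlation estimated from the arrays and with ranks, and fry was run too. Fry asks whether a list's genes move one way and, in its mixed form, whether they change in either direction. It compares a list with no change, so a pass in fry does not set a list apart from other genes. Of the 22 lists, 11 passed with the preset correlation (6 higher, 5 lower), 0 with an estimated correlation (smallest adjusted p 0.382; 1 list had an unadjusted p under 0.05), 12 with ranks, 0 in fry's directional test and 9 in its mixed test. Each list's median was also set among the medians of 10000 random lists of the same size, drawn within 50 bins of mean intensity. Intervals of medians came from 10000 bootstrap draws over genes, and genes are not independent replicates. Genes with an unadjusted p under 0.01 were counted per chromosome with Fisher's exact test. List scores are means of log2 values per array, and with 3 arrays against 3 an exact permutation p cannot go below 0.1.

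The design, the 21 named lists, the X-linked set and the rule for named genes were fixed before the data were examined. The named lists were Elongator, wobble uridine modification, undifferentiated and differentiating spermatogonia, chromosome axis and synapsis, meiotic recombination, pachytene spermatocytes, spermatids, the piRNA pathway, Sertoli, Leydig, peritubular myoid, macrophage, endothelial and erythrocyte markers, epididymis, adipocytes, p53, ATF4 with the unfolded protein response, the mitotic cell cycle and Y-linked genes. The rule names the measured Elongator subunits; among clusters past the threshold with separate groups, up to 10 with the largest rise and 10 with the largest fall; where fewer than 3 pass in a direction, the 5 with the smallest p, said not to pass; and for each list its 3 largest members past the threshold or, where none passes, the 2 with the smallest p. Predicted genes and repeat families were counted and not named. Genes named besides these are said to be chosen after their values were seen.

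The procedure was tested on simulated data made from the real clusters' means and spreads. Of 100 clusters changed 2-fold 94% were recovered, and of 100 changed 1.41-fold 79%, with 7 false calls among 180. These clusters were drawn at random and varied independently. The shares recovered do not hold for clusters with a larger spread or with deviations shared between genes. In 20 simulations, a list of independent genes shifted by -0.3 was called in 20 with either correlation. A list whose genes were correlated at 0.3 but not shifted was called in 7 with the preset correlation and in 0 with the estimated one. No shifted list of correlated genes was simulated. The power of the test with an estimated correlation is therefore not known for the pachytene list, whose estimated correlation was 0.386. Alternatives were: arrays centred on their medians, quantile normalisation again, all rows of the table, 1 cluster per gene, dim clusters left out (below the 30th percentile of mean value), an intensity trend with a robust prior, array weights, the replicate number as a block, each array left out in turn, thresholds of 0.01 and 0.1, limma's treat at 1.2-fold, and the other forms of the list test.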

Results

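Gene expression was compared between testes of control mice and of knockout mice, taken at postnatal day 15. At this age the first wave of meiosis has brought germ cells as far as pachytene spermatocytes. RNA of 3 control and 3 knockout samples was hybridised to 6 Affymetrix mouse gene arrays, each measuring 35556 transcript clusters (sets of probes that together read 1 transcribed region). Of these, 21789 clusters that carry 1 gene symbol were tested, and they stand for 19938 genes. The median value of an array lay between 8.075 and 8.1 on the log2 scale, and the lowest correlation between arrays, rounded, was 0.997 within a group and 0.996 across groups. The precision is limited by the number of arrays. The labels do not say whether the replicates are separate animals, so the p-values measure only the spread between these samples, which may be technical.

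The comparison of knockout with control testes asks which transcripts differ between the genotypes. Nell2, which encodes a secreted glycoprotein made by testicular germ cells, fell by 0.80 on the log2 scale in the knockout (SE 0.055, fold 0.574, adjusted p = 0.0139). Its transcript cluster, 10431812 on chromosome 15, averaged 9.86 ± 0.074 (SD, n = 3) in control and 9.06 ± 0.060 in knockout arrays. Tcl1, which encodes a co-activator of the AKT kinase, rose by 0.51 (SE 0.045, 1.43-fold, adjusted p = 0.0474), from 7.42 ± 0.047 to 7.93 ± 0.035 in cluster 10402514 on chromosome 12. The X-linked transcript 1700080O16Rik (cluster 10604557) rose by 0.87 (SE 0.054, 1.83-fold, adjusted p = 0.0126), from 8.81 ± 0.091 to 9.69 ± 0.0058. This last transcript falls outside the rule for named genes and was chosen after its values were seen. In each of these genes the 3 knockout values lay on one side of the 3 control values.

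These were the 3 clusters past an adjusted p of 0.05 in limma, 2 higher and 1 lower in the knockout, of which 2 changed at least 1.5-fold and 0 at least 2-fold. At an unadjusted p under 0.05 there were 2299 clusters (10.6%, against about 1089 by chance), 893 higher and 1406 lower. The knockout and control values did not overlap in 15.3% of clusters, where chance gives 10%. Among clusters without overlap, 38 were at least 1.5-fold lower and 3 at least 1.5-fold higher in the knockout, and 8 clusters were at least 2-fold lower at any p against 0 higher. The count of called clusters rested on the method and the choice of arrays. It was 0 with the replicate number as a block, with all rows of the table tested, at an adjusted p under 0.01 and with treat at 1.2-fold, 6 with dim clusters left out, and 7 with an intensity trend and robust prior. Without control replicate 1 it was 52 (49 lower and 3 higher, 43 of them at least 1.5-fold and 12 at least 2-fold), without control replicate 2 it was 1, and without control replicate 3 or any 1 of the knockout replicates it was 0. The 52 clusters held the 3 called with all arrays and 2 members of the pachytene spermatocyte list described below, Tcp11 and Adam3, named after their values were seen. The adjusted p of Nell2 ranged from 6.65e-04 to 0.219 over all settings tried, that of Tcl1 from 0.0161 to 0.370 and that of 1700080O16Rik from 5.95e-04 to 0.0966, with log2 differences of -0.84 to -0.77, 0.50 to 0.54 and 0.82 to 0.91.

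The genes with the next smallest p-values in each direction had separate groups of values. Tnfaip6, which encodes a secreted hyaluronan-binding protein, was 0.79 higher in the knockout (SE 0.074, adjusted p = 0.0590). The next smallest p-values on the higher side belonged to Nefm, a neurofilament subunit (0.35), Chac1, a glutathione-degrading enzyme (0.38), Slc7a3, a transporter of cationic amino acids (0.44), and the homeobox gene Barhl2 (0.39), with adjusted p-values of 0.120 to 0.220. On the lower side, Stard6, a lipid-transfer protein of germ cells, differed by -0.74 (SE 0.076, adjusted p = 0.0901), and its other cluster by -0.76. Kif27, a kinesin (-0.34), Bub1b, a kinase of the spindle checkpoint (-0.37), Lef1, a transcription factor of Wnt signalling (-0.34), and Wdr17 (-0.49) followed, with adjusted p-values of 0.188 to 0.220. None of these 10 passed the threshold in the main fit. Under other settings Tnfaip6 passed in 5, Stard6 in 3 and Bub1b in 1, the lowest adjusted p-values being 0.00905, 0.00905 and 0.0440, each with an intensity trend and robust prior.

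Subunits of Elongator, a complex that modifies wobble uridines of transfer RNAs, differed little between the genotypes. Elp2 differed by -0.02, Elp3 by -0.02, Elp4 by 0.06, Elp5 by -0.07 and Elp6 by 0.04 on the log2 scale, with standard errors of 0.040 to 0.050 and adjusted p-values of 0.580 to 0.932. The signs of Elp2 and Elp3 were not kept when the arrays were centred on their medians (0 and 0.0033). As a list, these 5 subunits had a median of -0.017 (adjusted p = 0.950 in camera and 0.952 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. The list of wobble uridine modification had a median of -0.037 over 13 genes (adjusted p = 0.601, and 0.754 with an estimated correlation), and 0 members passed either adjustment. The smallest p-values among its members were those of Nfs1, a cysteine desulfurase (-0.10), and Ctu1, which adds sulfur to wobble uridines (0.10).

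Genes that germ cells switch on in pachytene were lower in the knockout as a group. Of 34 measured genes of the pachytene spermatocyte list, 32 lay below and 2 above the control mean, with a median difference of -0.28 (median fold 0.825). The list passed camera with its preset correlation (adjusted p = 7.89e-13) and did not pass with the correlation estimated from these arrays (adjusted p = 0.382 with an estimated correlation). Nor did it pass fry's mixed test of change in either direction (adjusted p = 0.0707). At an unadjusted p under 0.05, 20 members were lower and 0 higher, while 0 passed over all genes and 0 adjusted over the list alone, where the smallest adjusted p was 0.0525. The members with the smallest p were Cks2, a binding partner of cyclin-dependent kinases (-0.21, SE 0.049), and Ccna1, the meiotic cyclin A1 (-0.27, SE 0.066). Larger differences, chosen after their values were seen, were those of Crisp2, a sperm cysteine-rich secretory protein (-0.86, SE 0.36), Ldhc, the testis lactate dehydrogenase (-0.75, SE 0.23), Tcp11 (-0.74, SE 0.23) and Piwil1 (-0.67, SE 0.23).

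The control arrays differed among themselves in these genes. Relative to the control mean, the mean of the pachytene list was -0.24, 0.18 and 0.06 in control replicates 1, 2 and 3, and -0.40, -0.38 and -0.21 in the 3 knockout replicates, so the groups overlapped (9.48 ± 0.22 against 9.15 ± 0.10, SD, n = 3, exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible). Without control replicate 1, 24 of the 34 genes were lower when adjusted over the list alone, and without knockout replicate 3, 3 were. The median stayed between -0.37 and -0.19 whichever array was left out.

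**Figure D1:**
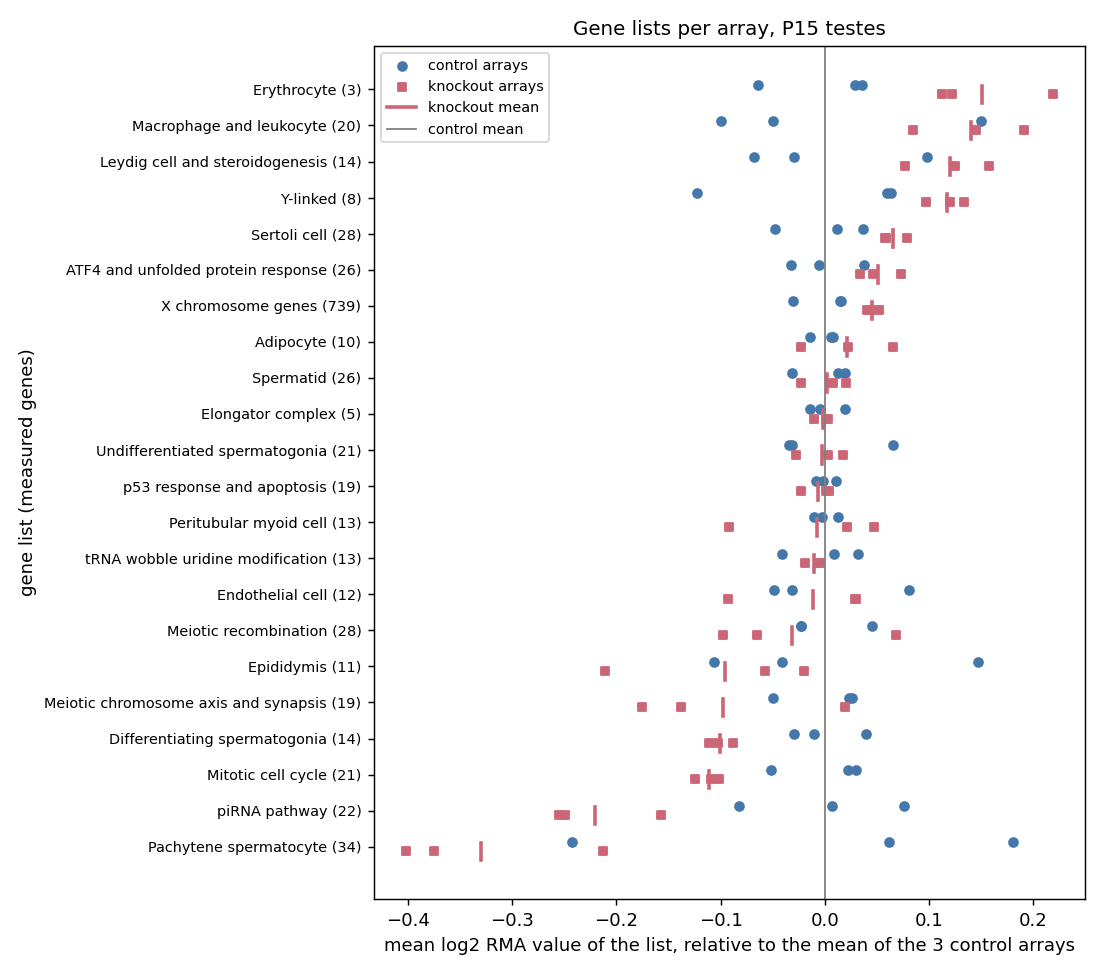
Mean log2 RMA value of each gene list in each of the 3 control arrays (circles) and 3 knockout arrays (squares), relative to the control mean (grey line); the short bars are knockout means, and the number of measured genes is in brackets. In the piRNA pathway list the knockout arrays lie at -0.25, -0.26 and -0.16, below all control arrays, whereas in the pachytene spermatocyte list control replicate 1 lies at -0.24, among the knockout arrays.

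The piRNA pathway, which silences transposons in germ cells through PIWI proteins and their small RNAs, was lower in all 3 knockout arrays than in any control array. Of 22 measured genes 21 lay below the control mean, with a median of -0.18 (median fold 0.885). None passed over all genes, and 14 fell when adjusted over the list alone. The smallest p-values were those of Tdrd1, a tudor-domain scaffold of germ granules (-0.40, SE 0.059, adjusted p = 0.00341 over the list and 0.239 over all genes), and Henmt1, the methyltransferase that protects piRNA ends (-0.32, SE 0.050, adjusted p = 0.00341 over the list). The Argonaute-family members Piwil1 (-0.67), Piwil2 (-0.18) and Piwil4 (-0.28), and Mael (-0.22) and the germ-cell helicase Ddx4 (-0.20), chosen after their values were seen, were among the 14. The list passed camera with the preset correlation (adjusted p = 7.89e-13), with an adjusted p = 0.382 with an estimated correlation. The count of 14 fell to 3 without knockout replicate 1, 6 without knockout replicate 2, 7 without control replicate 2 and 8 without control replicate 3. The list shares Piwil1 and Tdrd6, 2 genes, with the pachytene list.

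**Figure D2:**
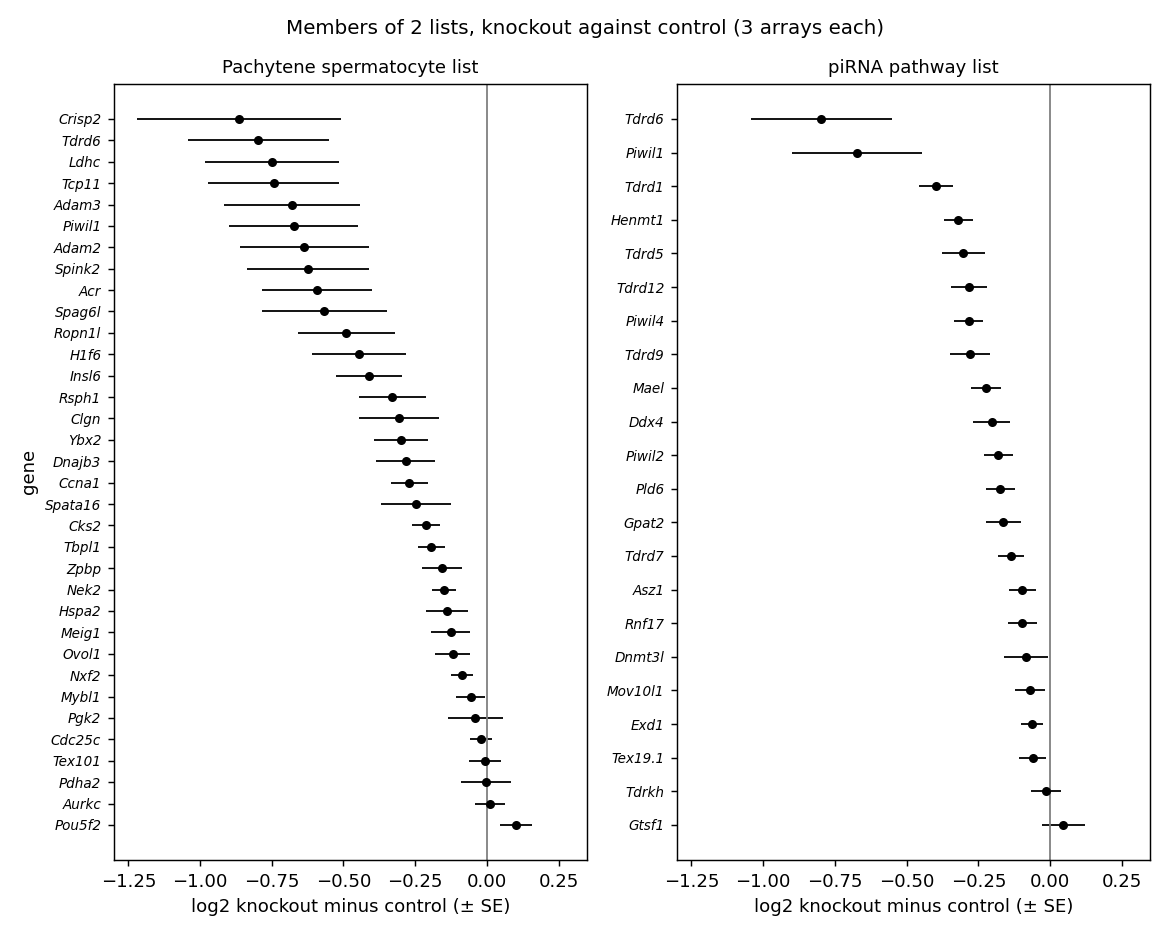
Log2 difference (knockout minus control, 3 arrays each) with its standard error for every measured gene of the pachytene spermatocyte list (left, 34 genes) and the piRNA pathway list (right, 22 genes). Points left of the grey line are lower in the knockout, 32 genes on the left panel and 21 on the right.

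Genes of mitosis were lower in all 3 knockout arrays too. The mitotic cell cycle list had a median of -0.12 over 21 genes, 18 below and 3 above the control mean (adjusted p = 9.23e-08, and adjusted p = 0.382 with an estimated correlation). No member passed over all genes, and 5 fell when adjusted over the list alone, led by the checkpoint kinase Bub1b (-0.37, SE 0.047, adjusted p = 0.00190 over the list) and the mitotic kinesin Kif20a (-0.21, SE 0.041). The others were Ccnb2, Aurka and Birc5, chosen after their values were seen. The count of 5 was 14 without control replicate 3, 2 without control replicate 2 or knockout replicate 1, and 1 without any other single array.

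Spermatogonial genes were tested in 2 lists. That of differentiating spermatogonia was lower, with a median of -0.085 and 11 of 14 genes below the control mean (adjusted p = 0.0109, and adjusted p = 0.382 with an estimated correlation). Adjusted over the list alone 3 genes fell, against 0 over all genes: Dmrtb1, a regulator of the switch from mitosis to meiosis (-0.36, SE 0.076), Rec8, a meiotic cohesin (-0.40, SE 0.11), and Sohlh2, a transcription factor of differentiation (-0.22, SE 0.061), named after its values were seen. The list did not pass without control replicate 1 (median -0.066, adjusted p = 0.0633, with a range of 0.00378 to 0.382 over its alternatives), and its 3 members came to 0 without control replicate 1, control replicate 2 or knockout replicate 1, and to 1 without knockout replicate 2 or 3. The list of undifferentiated spermatogonia had a median of -0.027 over 21 genes (9 above, 12 below) and did not pass camera (adjusted p = 0.879, and 0.952 with an estimated correlation). In fry's mixed test, of change in either direction, the list did pass (adjusted p = 3.84e-04). Its members went both ways when adjusted over the list alone, where 2 rose and 1 fell against 0 over all genes. Gfra1, the GDNF receptor of stem spermatogonia, rose by 0.39 (SE 0.062, adjusted p = 0.00675 over the list) and Etv5, a transcription factor of the same cells named after its values were seen, by 0.25 (SE 0.055). Sall4, a zinc-finger factor of spermatogonia, fell by 0.30 (SE 0.063, adjusted p = 0.0161 over the list). These counts were 1 and 0 without knockout replicate 2, and in other leave-outs between 2 and 3 higher and between 1 and 2 lower.

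Genes of meiotic chromosomes had small differences. The list of the chromosome axis and synapsis had a median of -0.073, with 16 of 19 genes below the control mean (adjusted p = 6.30e-04, and adjusted p = 0.509 with an estimated correlation). It did not pass fry's mixed test (adjusted p = 0.183), and 0 members passed over all genes or adjusted over the list alone. Stag3 (-0.22, SE 0.053) and Rec8 (-0.40, SE 0.11), both meiotic cohesin subunits, had its smallest p-values. The groups overlapped: relative to the control mean, knockout replicates 1 and 2 lay at -0.18 and -0.14 but knockout replicate 3 at 0.020, above control replicate 1 (-0.049). Its median was -0.055 without knockout replicate 1, where it did not pass (adjusted p = 0.0992, range 7.85e-09 to 0.509 over its alternatives), and -0.12 without knockout replicate 3, where 4 members passed over the list alone. The meiotic recombination list had a median of -0.015 over 28 genes and did not pass camera (adjusted p = 0.109, and 0.754 with an estimated correlation). It passed fry's mixed test of change in either direction (adjusted p = 0.0176). Adjusted over the list alone, 2 of its members fell against 0 over all genes: Spo11, which makes the double-strand breaks of meiosis (-0.35, SE 0.063, adjusted p = 0.0207), and Mei1, needed for those breaks (-0.23, SE 0.049, adjusted p = 0.0301). That count was 5 without knockout replicate 3, where the list passed (median -0.10, adjusted p = 3.28e-04, range 3.28e-04 to 0.817), and 0 without any other single array. Spermatid genes had a median of 0.0067 over 26 genes (adjusted p = 0.879, and 0.952 with an estimated correlation), with 0 members past either adjustment. Their mean value was 6.69, below the array medians, and at this age germ cells have come only as far as pachytene. The list could therefore hardly show a change in spermatids. The protamine gene Prm1 (0.21) and the X-linked Tsga8 (0.15) had the smallest p-values.

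Markers of some somatic cells were higher in the knockout, by small amounts. Of 28 Sertoli cell genes 25 lay above the control mean, with a median of 0.07 (1.05-fold, adjusted p = 2.29e-04, and adjusted p = 0.450 with an estimated correlation), and all 3 knockout arrays lay above the control arrays. Adjusted over the list alone 2 rose, against 0 over all genes: Kitl, the stem cell factor that Sertoli cells present to germ cells (0.28, SE 0.041, adjusted p = 0.00586), and Nr5a1, a nuclear receptor of gonadal somatic cells (0.18, SE 0.038, adjusted p = 0.0270). The median was 0.031 without control replicate 2, and whichever array was left out, 1 gene passed over the list. Of 20 macrophage and leukocyte genes 18 were above the control mean, with a median of 0.13 (adjusted p = 4.26e-05, and adjusted p = 0.411 with an estimated correlation). The macrophage list did not pass fry's mixed test (adjusted p = 0.202), and the exact permutation p of its score was 0.3. The microglial and macrophage receptor gene Cx3cr1 (0.16) and the complement gene C1qc (0.16) had the smallest p-values. In the macrophage list 0 members passed over all genes or adjusted over the list alone, and 9 passed over the list without control replicate 3, whose macrophage score (0.15 above the control mean) lay among the knockout arrays (0.085 to 0.19).

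Leydig cell and steroidogenesis genes had a median of 0.12 over 14 genes (adjusted p = 0.0772, and 0.411 with an estimated correlation), which did not pass. It passed on ranks (adjusted p = 0.0366) and without knockout replicate 3 (median 0.13, adjusted p = 0.0421). Within that list Hsd17b3, which makes testosterone, fell by 0.43 when adjusted over the list alone (SE 0.091, adjusted p = 0.0282, against 0.292 over all genes), the 1 member to do so, while Cyp11a1, which makes pregnenolone, was 0.37 higher (SE 0.11, not past either adjustment). The call of Hsd17b3 was lost without control replicate 3 or knockout replicate 1. On the higher side, 1 member passed over the list alone without control replicate 1 and 2 without knockout replicate 3. The 3 measured erythrocyte genes had a median of 0.13 (adjusted p = 0.0357, and adjusted p = 0.382 with an estimated correlation), and their score lay above all control arrays in all 3 knockout arrays. Alas2 (0.28) and Slc4a1 (0.13) led, with 0 past over all genes or adjusted over the list alone. In fry's mixed test the erythrocyte list did not pass (adjusted p = 0.282). That list did not pass without control replicate 1, control replicate 3 or knockout replicate 1 (adjusted p = 0.0633, 0.0634 and 0.0992, range 0.0234 to 0.382). Over the list alone, 1 erythrocyte gene rose without control replicate 3. Markers of peritubular myoid cells (median -0.013, adjusted p = 0.879), endothelial cells (-0.0033, or 0.011 after quantile normalisation again, adjusted p = 0.879), the epididymis (-0.047, adjusted p = 0.302) and adipocytes (0.010, adjusted p = 0.879) did not pass, and 0 of their members passed over all genes or adjusted over the list alone. The members with the smallest p were Des (0.15) and Tagln (-0.15) for myoid cells and Esam (-0.12) and Vwf (0.077) for endothelium. For the epididymis they were Cst11 (-0.25) and Defb15 (-0.12), and for adipocytes Plin1 (0.12) and Pnpla2 (-0.077). Without knockout replicate 3, 1 adipocyte gene rose over its list alone.

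Among stress pathways, the list of ATF4 targets and the unfolded protein response was higher by a median of 0.047, with 19 of 26 genes above the control mean (adjusted p = 0.00807, and adjusted p = 0.509 with an estimated correlation). The groups overlapped: relative to the control mean, control replicate 1 lay at 0.038 and knockout replicate 3 at 0.033 (exact permutation p = 0.2). The ATF4 target Chac1 rose by 0.38 when adjusted over the list alone (SE 0.048, adjusted p = 0.00225), the 1 member to do so against 0 over all genes. Without control replicate 1, 2 members did so. Atf4 itself was 0.22 higher (SE 0.061) and did not pass either adjustment. The list did not pass without control replicate 2 (adjusted p = 0.0623) or knockout replicate 2 (adjusted p = 0.175, range 0.00155 to 0.509 over its alternatives). Genes of the p53 response and apoptosis had a median of 0.0033 and a mean of -0.0061 over 19 genes, and the camera test, which pointed to lower values, did not pass (adjusted p = 0.879, and 0.952 with an estimated correlation). The list passed fry's mixed test of change in either direction (adjusted p = 0.0235). Tnfrsf10b, a death receptor (-0.26), and Plk2, a polo-like kinase (0.22), had the smallest p-values, with 0 members past over all genes or adjusted over the list alone. Without control replicate 1, 1 member rose and 1 fell over the list alone. The median of the p53 list ranged from -0.035 to 0.015 with 1 array left out.

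Genes on the sex chromosomes, which are silenced in pachytene spermatocytes, were tested as sets. The 739 X-linked genes were higher in the knockout by a median of 0.047 (95% bootstrap interval over genes 0.043 to 0.053), with 520 above and 209 below the control mean, or 70.4% above against 50.3% of autosomal genes, whose median was 0.0033. Every knockout array lay above every control array. The set passed camera with the preset correlation (adjusted p = 4.63e-06), with an adjusted p = 0.411 with an estimated correlation. Of its members, 1 passed over all genes (1700080O16Rik) and 2 adjusted over the list alone, the other being Slc7a3. Ccnb3, a meiotic cyclin, was 0.47 higher and the testis antigen Prame 0.29 higher, neither past the threshold and both chosen after their values were seen. Without control replicate 2 the median was 0.028. The Y-linked list had a median of 0.097 over 8 genes (adjusted p = 0.0327, and adjusted p = 0.536 with an estimated correlation), and did not pass fry's mixed test (adjusted p = 0.0533). Adjusted over the list alone, Zfy1 and Zfy2, zinc-finger genes of the Y chromosome, each rose by 0.34 and Uba1y, a ubiquitin-activating enzyme named after its values were seen, fell by 0.15, against 0 members over all genes. The Y-linked median was 0.028 without control replicate 2 (adjusted p = 0.113), 0.16 without control replicate 3, and 0.092 without knockout replicate 3 (adjusted p = 0.0878, range 0.0133 to 0.536 over its alternatives). Uba1y passed only with all arrays or without control replicate 3, and 1 of the 2 higher genes passed without any 1 knockout array.

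**Figure D3:**
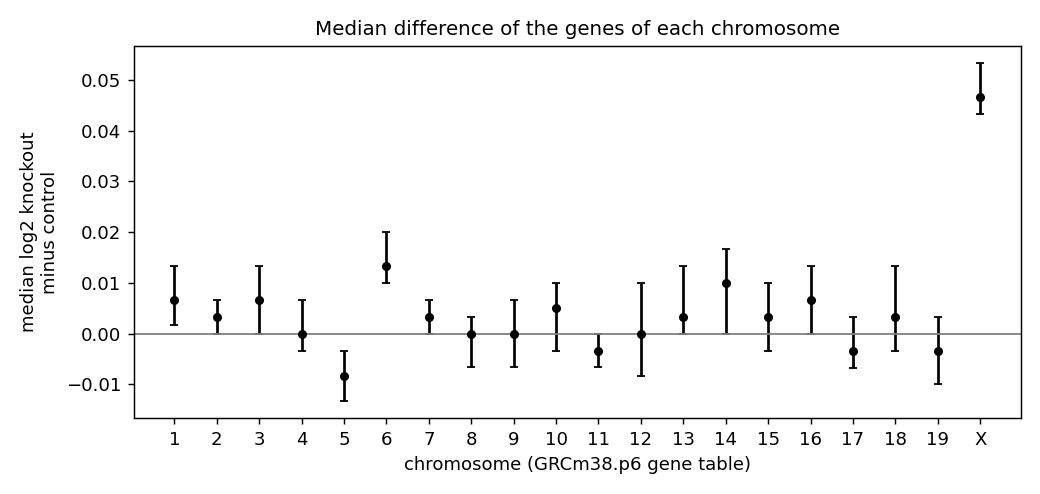
Median log2 difference (knockout minus control, 3 arrays each) of the tested genes of each autosome and of the X chromosome, with the 95% bootstrap interval over genes; chromosomes are those of the GRCm38.p6 gene table. The X chromosome lies at 0.047, and the autosomes lie between -0.0083 (chromosome 5) and 0.013 (chromosome 6).

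The 3 called genes lay on chromosomes 12, 15 and X, 1 on each, too few to test by chromosome. At an unadjusted p under 0.01, a threshold added after seeing the data, chromosome X held 28 genes, 23 of them higher in the knockout, which was 3.79% of its genes against 2.82% elsewhere (adjusted p = 0.497, Fisher's exact test, two-sided), and no chromosome passed.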

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

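The unadjusted threshold of 0.01 for genes by chromosome was chosen after the result was seen; all other alternatives were planned. Centring the arrays or normalising them by quantiles again moved the median of all clusters by 0.02 and 0.005. Over 766 alternatives of named genes 731 kept their direction and side of the threshold, 20 lost and 10 gained a call, and 5 changed direction. Over 176 alternatives of the 11 called lists 155 kept both, 21 lost the call and 0 changed direction. Over 175 of the other lists 156 kept both, 4 gained a call and 15 changed direction. These counts overstate how stable the lists are. Testing all rows, 1 cluster per gene and an intensity trend with a robust prior left every list test identical to the main one. Those settings could not change a list, and an estimated correlation could not change its direction. Background was not known, so which clusters lie near it was not tested. With dim clusters left out the epididymis list and 3 named genes (Nefm, Tsga8 and Defb15) gave no value, and with 1 cluster per gene the cluster reported for Stard6 gave none.

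The count of 3 clusters (2 higher, 1 lower, 2 at least 1.5-fold) became 0 (0 higher, 0 lower, 0 at least 1.5-fold) when all rows of the table were tested, at an adjusted p under 0.01 and with treat at 1.2-fold; outside the tested clusters, 0 of 13767 passed in limma and 834 had an unadjusted p under 0.05. It became 6 (3 lower, 5 at least 1.5-fold) with dim clusters left out and at an adjusted p under 0.1, and 7 (4 lower, 5 at least 1.5-fold) with an intensity trend and robust prior. With 1 array left out it ranged from 0 to 52, with 0 to 3 higher, 0 to 49 lower, 0 to 43 at least 1.5-fold and 0 to 12 at least 2-fold; the highest counts came without control replicate 1. Beyond fewer or more clusters tested, the cause was not tested.

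With the replicate number as a replicate block, 0 clusters passed (0 higher, 0 lower, 0 at least 1.5-fold), and the erythrocyte list, with a median of 0.13, did not pass (adjusted p = 0.0523, range 0.0234 to 0.382 over its alternatives); the block changed no other list's call. The deviations of equally numbered arrays correlated at 0.17, -0.054 and 0.17. Those of differently numbered arrays correlated at -0.23 to 0.084. Both values of 0.17 lay above that range and the value of -0.054 lay within it. Whether the numbers pair the samples therefore cannot be told from these correlations. The main fit did not use the numbers, and its called clusters depend on that choice.

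With the correlation estimated, 0 lists passed, at unchanged medians of -0.085 (differentiating spermatogonia), -0.073 (axis and synapsis), -0.28 (pachytene), -0.18 (piRNA), 0.07 (Sertoli), 0.13 (macrophage), 0.13 (erythrocyte), 0.047 (ATF4), -0.12 (mitotic), 0.097 (Y-linked) and 0.047 (X-linked). On ranks the Leydig list passed (median 0.12, adjusted p = 0.0366, range 0.0366 to 0.411), as it did without knockout replicate 3 (0.13, adjusted p = 0.0421), and with array weights the recombination list did (-0.044, adjusted p = 0.0361, range 3.28e-04 to 0.817).

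Arrays centred on their medians put Elp2 at 0, Elp3 at 0.0033 and the Elongator list at 0.0033, and without dim clusters the Elongator test turned direction at a median of -0.017. Quantile normalisation again turned the spermatid test (median 0.00069) and the endothelial list (0.011).

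With 1 array left out, values ranged from -0.057 to 0.0033 for Elp2, -0.047 to 0.0083 for Elp3 and -0.0050 to 0.06 for Elp6. List medians ranged from -0.047 to 0.0083 (Elongator), -0.043 to 0.012 (undifferentiated spermatogonia), -0.12 to -0.066 (differentiating), -0.12 to -0.055 (axis and synapsis), -0.10 to 0.0042 (recombination), -0.017 to 0.024 (spermatid), 0.096 to 0.15 (Leydig), -0.025 to 0.03 (myoid), -0.039 to 0.042 (endothelial), 0.087 to 0.17 (erythrocyte), -0.09 to 0.018 (epididymis), -0.0075 to 0.025 (adipocyte), 0.033 to 0.064 (ATF4) and 0.028 to 0.16 (Y-linked). The cause was not tested.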

Other observations

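The gene lists in this paragraph and the next were chosen only after the result was seen. So were the tests of the pachytene pattern, the splits of the gene lists, the somatic comparisons and the leave-out intervals for X-linked genes. Because the values were known when these gene lists were drawn up, their p-values describe the lists and give no independent support. Genes of the motile cilium and sperm tail, which germ cells begin to express in pachytene, had a median of -0.33 in the knockout, with 29 of 31 below the control mean, 15 with an unadjusted p under 0.05 and 0 past the threshold over all clusters (smallest adjusted p 0.287). Among them were Dnah2, an axonemal dynein (-0.33, SE 0.066), Spag16, a protein of the axoneme's central pair (-0.68, SE 0.17), and Hydin (-0.54, SE 0.16). The list passed camera with the preset correlation over the 5 lists added (adjusted p = 2.89e-11), with an adjusted p = 0.228 with an estimated correlation, and control replicate 1 (-0.24) again lay among the knockout arrays (-0.36, -0.34 and -0.21). Subunits of the sperm calcium channel CATSPER had a median of -0.14 over 9 genes, 7 below and 2 above the control mean (adjusted p = 0.00319, and adjusted p = 0.186 with an estimated correlation). Catspere2 had the smallest p (-0.29, SE 0.053). Catsperz (-0.80, SE 0.29), Catsperb (-0.79, SE 0.32) and Catsperd (-0.45, SE 0.14) differed more. Catsper1 and Catsper3 are also in the spermatid list. Proteases of the ADAM family in testis had a median of -0.0067 over 18 genes (adjusted p = 0.142, and 0.411 with an estimated correlation), with Adam32 at -0.96 (SE 0.28) and Adam5 at -0.88 (SE 0.35) beside members near 0.

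Immediate early genes respond within minutes to stimuli and to tissue handling. The mean of their list was higher in knockout replicate 3 than in any other array. It lay 0.42 above the control mean there, against 0.084 and 0.091 in the other knockout arrays. Over 14 genes the median was 0.15 (adjusted p = 0.00109, and adjusted p = 0.228 with an estimated correlation). Egr2 was 0.42 higher (SE 0.062) with a small spread. Nr4a1 was 0.64 higher with an SD of 1.04 in the knockout, and Nr4a2 0.56 higher with an SD of 0.83. Jun, Egr1, Fosb and Btg2 had knockout SDs of 0.22 to 0.28, and all other members 0.021 (Fos) to 0.13 (Junb). The high mean of knockout replicate 3 was therefore not shared by every member. Dusp1 (-0.08) and Atf3 (-0.03) were lower on average. Genes of MHC class II had a median of 0.11 over 6 genes (adjusted p = 0.135, and 0.444 with an estimated correlation) and were highest in knockout replicate 3 (0.48) and control replicate 3 (0.24).

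The lower pachytene list is the first pattern weighed. Intensity-dependent bias of the arrays is argued against, because the list's median of -0.28 stood at percentile 0 of 10000 random lists of like intensity, and so is a single array as its source, because the median nearest to 0 with any array left out was -0.19. A hypothesis is that the knockout samples hold fewer cells that have reached pachytene. It may hold with the somatic cells kept, but the pooled myoid and endothelial genes, which should then rise as the Sertoli genes do (0.07), had a median of -0.010 (interval -0.030 to 0.027), and the Sertoli score minus theirs overlapped between the groups (0.034 to 0.15 against -0.033 to 0.053), so this stays open, as does a loss with spermatogonia kept (median -0.027, interval -0.12 to 0.11). A lower level of these transcripts per cell and a difference in litter or exact age were not tested and stay open too.

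The higher X-linked genes are the second pattern. Intensity-dependent bias is argued against by percentile 100 among 10000 random lists. Without the 260 genes in families of 3 or more X-linked genes that share a symbol stem, the median was 0.047. This argues against those families as the whole source. The stem rule does not tell multicopy families from others, and a median over 739 genes could hardly rest on a few families. A single array as the whole source is argued against in these arrays, because every knockout array lay above every control array. The median also stayed at 0.028 or higher with any array left out. The lowest interval in these leave-outs began at 0.022, but it is over genes and does not measure the spread between arrays. The rule set before the data were examined, on how far the median may fall, did not decide. That control replicate 2 sets part of the shift cannot be told apart, since the median was 0.028 without it and up to 0.053 without another. A hypothesis is that the knockout samples hold fewer cells with a silenced X chromosome, which would raise X-linked genes no more than somatic markers. The autosomal Sertoli genes exceeded the X-linked genes by 0.027 (interval -0.0017 to 0.047). The pooled myoid and endothelial genes (median -0.010, interval -0.030 to 0.027) lay below them, which goes against the hypothesis, but the X-linked score minus theirs overlapped between the groups (0.0047 to 0.14 in knockout against -0.030 to 0.032 in control arrays), so it stays open.

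The splits of the 6 arrays into 3 and 3 number 10, the real one included, too few for a share under 0.05. The real split called 3 clusters and the highest other 0, so 1 of 10 gave as many. For the gene lists, 2 of 10 splits gave as many: the real one passed 11 lists, and the split of control replicates 1 and 2 with knockout replicate 3 against the rest passed 11 as well.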
